A study of Arabidopsis thaliana with 42 samples.

How the data were processed

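The series holds 42 libraries of stranded mRNA sequencing from whole Arabidopsis seedlings, in 14 groups of 3 set by genotype, treatment and time. Per the labels, seedlings were grown for 10 days at 23 °C by day and 18 °C by night with 16 h of light and 8 h of dark, moved to liquid medium 3 h after the light came on, and heated at 44 °C in light with or without cycloheximide. Sequencing was paired-end with 150 cycles, and each library was run on 2 lanes. Samples were put into groups from their labels alone. Replicate libraries are separate samples per the series text, so p-values measure the spread between them.

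The main table holds a score per transcript and lane, which the authors deposited as normalized counts. The values are whole numbers, their 75th percentile is nearly equal in all columns (156 to 191), and in the 36 of 84 columns with a fitted step over 1 (to 2.44) low values skip whole numbers, at least 99.4% of them lying on the step, so they were read as counts divided by a size factor per column and then rounded by the authors. In the other 48 columns the step (from 0.613) was fitted from how often each low number occurs, and skipped numbers cannot show it. They are not counts, so no count test was possible, and the number of reads was estimated per lane from the step. Programs named in the submitters' processing notes are kallisto and sleuth, with the TAIR10 build; their versions, roles and scaling method are not given in the sources used here. The 2 tables of comparisons hold log2 fold changes and adjusted p-values per transcript that the authors deposited; the base and the sign were checked against the normalized values, and the tool behind them is not given in the sources used here. They list 46060 transcripts with values, 35376 of which were compared with tests here.

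The 2 lanes of a library were averaged, and their correlation on the log2 scale was at least 0.779. The table lists 48359 transcripts of 27655 genes, 2299 of them at 0 in every column and 10695 genes with 2 or more transcripts. An exact 0 can be a failed estimate, so genes or transcripts at 0 throughout a group are given as listed at 0, without a fold. Transcript identifiers were matched to the TAIR10.1 reference, which gave 48148 matches (99.6%), gene names, positions and exon junctions. Of the 48147 transcripts with a coding sequence 48068 (99.9%) reached the annotated stop in frame when read from the genome sequence.

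Transcripts were summed to genes, a pseudocount of 1 was added and log2 was taken, so fold changes are on the log2(value + 1) scale and understate changes of low genes. Genes with at least 10 in at least 3 libraries were kept (20747). Tests used limma 3.58.1 in R 4.3.3 with a mean for each of the 14 groups, a trend of variance with level and Benjamini-Hochberg adjustment within each comparison; a call needs an adjusted p under 0.05 and at least a 2-fold change. The 23 comparisons of genes were each heated time against 0 min in wild type and in upf, upf against wild type at each time and as a mean, CHX plus heat against heat at each time and as a mean, and the difference of the heat responses of the genotypes at each time. There is no unheated CHX group, so the CHX effect is always that in heated seedlings. Nor is there an unheated group after 0 min. A heat effect here therefore cannot be told apart from an effect of time since 0 min, in medium or of day. Transcript usage was tested with limma's diffSplice, the log2 change of each transcript against that of its gene's other transcripts, over 22958 transcripts and 15 comparisons. Early stops were tested with Fisher's exact test, 2-sided, and adjusted over the 15 comparisons. Fisher's test treats transcripts as independent. Transcripts of 1 gene move against each other in usage, so its intervals may be too narrow and its p-values too small. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

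The main design, the rule for named genes and the 19 gene lists were written before the data were examined. The lists, with their members, are small heat shock proteins (16), chaperones (25), heat shock and related factors (25), unfolded protein response (21), SR proteins (20), splicing factors (16), NMD factors (14), mRNA decay (15), known NMD targets (13), conserved upstream reading frames (17), immunity (26), rapidly induced genes (27), cytosolic ribosome (25), photosynthesis of the shoot (22), clock (14), redox (11), root markers (12), seed maturation (11) and reference genes (9). Before testing, 6 members whose locus and symbol disagreed in the reference were dropped. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 19 lists within a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. Named genes are UPF1, UPF3 and the known NMD targets; for wild type at 15 and 90 min, the upf mean, the CHX mean and the response difference at 90 min, the 6 largest increases and 6 largest decreases past the threshold with a higher group mean of at least 100, with replicates that do not overlap or, for the means, the same direction at every time; and up to 4 members per list with the largest change past the threshold, or the 2 most abundant where none passed. For usage they are the 6 most raised and 4 most lowered transcripts for the upf mean, the CHX mean and wild type at 30 min in genes with a total of at least 100, and the 8 largest changes of SR, splicing, NMD factor and heat shock factor transcripts in upf. Some members of the NMD lists are not reported here.

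The gene test, the usage tests and camera at the preset correlation were first run on simulated data made from the wild type at 15 and 0 min. In these data 200 genes or transcripts were changed. Fisher's exact test, fry and camera with an estimated correlation were not simulated. Over 20747 genes none of the 1.5-fold changes were called (50.7% by adjusted p alone), 47.8% of the 2-fold (86.6% by adjusted p alone) and 98.5% of the 4-fold, with 4 unchanged genes called. A true 2-fold change lies at the fold threshold, so its estimate often falls below that threshold at any spread. Over 22958 transcripts usage calls recovered 1.49% of 2-fold, 26.9% of 4-fold and 77.3% of 16-fold changes, so small usage changes are mostly missed. A further 85 transcripts that were not themselves changed were called. Other transcripts of the changed genes were not left out of this count, and their usage moves too, so it does not measure false calls alone. The folds simulated for usage were raised after a try at the gene folds recovered few. Of a pair of simulated lists limma's camera called the list of raised genes and did not call the unchanged list. The simulated genes varied independently, so this pair cannot show how camera treats lists whose genes vary together.

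Alternatives tried were each library left out in turn, no filter or at least 50, pseudocounts of 0.5 and 5, transcripts as deposited without summing, median-of-ratios and total scaling, only the compared libraries, no trend, the replicate number as a block, the log2 ratio to the gene's other transcripts, stops over 55 and 100 nt before the last junction, the upf effect at the same time, and calls without a fold threshold. Chosen after seeing the data were leaving out 6 libraries that stand apart from their group, treating the 84 lanes as separate, and reading the stop from the start of the gene's longest coding sequence. A library stands apart where both its distances to its group's others are over 2 times the distance between those; it holds for upf at 30 min replicate 3 and 90 min replicate 1, wild type at 30 and 45 min replicate 3, and CHX at 45 and 90 min replicate 3.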

Results

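Transcript levels were measured by stranded mRNA sequencing in 10-day-old Arabidopsis seedlings held at 44 °C. The wild type was Columbia-0. The mutant, called upf here, carries both upf3-1 and upf1-5, and the labels describe it as compromised in nonsense-mediated decay (NMD), the pathway that removes transcripts with an early stop codon. Both genotypes were sampled before heat and after 15, 30, 45 and 90 min of heat. Wild-type seedlings were also heated for the same 4 times in medium with cycloheximide (CHX), an inhibitor of translation, at 10 µg/L per the labels, a unit that was not checked here. The 14 groups held 3 libraries each, 42 in all, and per the series text each replicate came from multiple plants. Summed normalized counts rose with heat, from 16.2 ± 0.400 M (mean ± SD, n = 3, M for 1e+06) in unheated wild type to 27.7 ± 1.46 M at 90 min, and stood at 20.5 ± 1.51 M at 90 min with CHX. Read numbers, estimated from the spacing of low values, ran from 20.4 to 76.4 M per library with a median of 42.7 M. After summing transcripts to genes, 20747 genes passed the filter on low values. A gene is said to have risen or fallen where limma's adjusted p was under 0.05 and the change was at least 2-fold.

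The transcript totals of both mutated genes were low in every upf library, as the labels imply. UPF1 (AT5G47010, chromosome 5, 19071824 to 19079453, plus strand of TAIR10.1), the RNA helicase at the centre of NMD, averaged 2150 ± 140 normalized counts (n = 3) in unheated wild type and 636 ± 161 in unheated upf. That is a log2 change of -1.78 (SE 0.20, adjusted p = 2.9e-08). UPF3 (AT1G33980, chromosome 1, 12351566 to 12355173, plus strand), which links the helicase to exon junctions, averaged 654.5 ± 13.6 and 170 ± 25.8, a log2 change of -1.95 (SE 0.14, adjusted p = 2.9e-12). In the heated groups UPF1 averaged 1925 ± 185, 1728 ± 397, 1920 ± 149 and 1976 ± 157 in wild type at 15, 30, 45 and 90 min, and 499 ± 13.01, 500 ± 77.1, 544 ± 64.7 and 500.0 ± 37.1 in upf. UPF3 averaged 540 ± 20.5, 494 ± 24.1, 505 ± 47.0 and 532 ± 26.0 in wild type, and 147.5 ± 9.26, 130 ± 22.8, 148 ± 15.41 and 137 ± 9.84 in upf. Over the 5 times the mean change was -1.86 (SE 0.09, adjusted p = 5.8e-19) for UPF1 and -1.89 (SE 0.06, adjusted p = 4.6e-23) for UPF3. With CHX at 15, 30, 45 and 90 min UPF1 averaged 1721 ± 366, 2002 ± 359, 2028 ± 516 and 2139 ± 606, and UPF3 797 ± 22.4, 872 ± 90.31, 763 ± 204 and 963 ± 70.0. The mean CHX effect was 0.04 (adjusted p = 0.720) for UPF1 and 0.70 (SE 0.07, adjusted p = 1.7e-10) for UPF3, the latter below the 2-fold threshold. The authors' deposited table gives log2 changes of -1.76 (adjusted p = 3.8e-37) for the UPF1 transcript and -2.12 (adjusted p = 1.5e-33) for UPF3 transcript AT1G33980.1 in unheated upf. The other UPF3 transcript, AT1G33980.2, averaged 23.8 ± 11.03 there and 23.7 ± 39.7 in wild type.

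**Figure D1:**
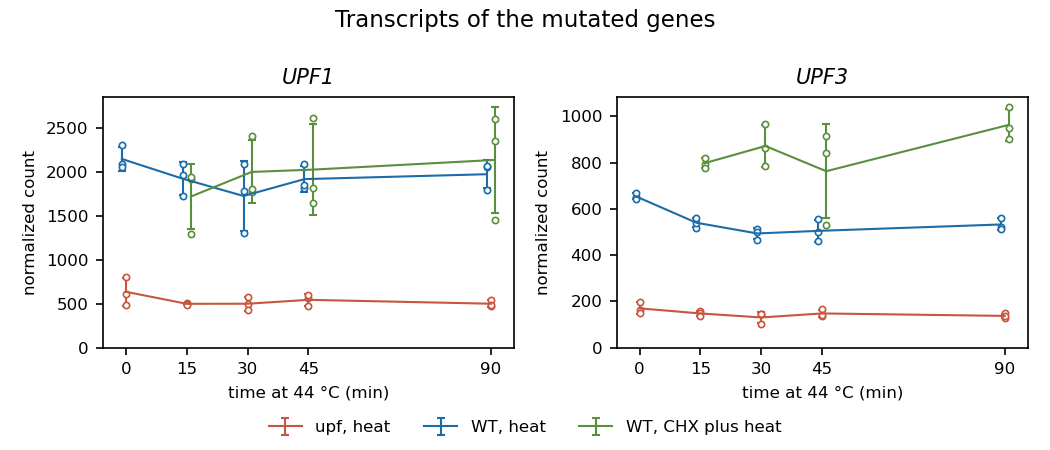
Normalized counts of UPF1 and UPF3 (vertical axes) against minutes at 44 °C (horizontal axes) in upf, wild type and wild type with CHX. Points are libraries, lines join group means and bars are ± SD (n = 3); before heat UPF1 averaged 636 in upf and 2150 in wild type, and UPF3 170 and 654.5.

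The comparison of heated with unheated wild type asks which transcripts the seedlings gained or lost as heat went on. Unheated seedlings were sampled at 0 min only, so changes with heat and with time alone cannot be told apart. Within 15 min the lists of chaperones and heat shock factors had risen. HSP101 (AT1G74310), the disaggregase needed for heat tolerance, went from 619 ± 129 to 60439 ± 1662 normalized counts (n = 3 each), and HSFA2, a heat-induced heat shock factor, from 112 ± 26.0 to 20775 ± 940. In all, 1850 genes rose and 1093 fell at 15 min. The largest increases with separate replicates were those of DDF1, an AP2/ERF factor (log2 change 10.97, SE 0.39, adjusted p = 3.2e-22), RRTF1, a redox-responsive factor (10.38), the calmodulin-like gene CML37 (8.77), DDF2 (8.57) and HSP17.6A_CI, a small heat shock protein (8.35). The AP2/ERF gene AT5G51190 averaged 1857 ± 138 at 15 min and was listed at 0 in every unheated library. Of the largest decreases, 5 were of SAUR-like genes, a family of auxin-induced transcripts: AT1G29460 (-4.83, SE 0.44, adjusted p = 2.9e-11), AT4G38860 (-4.58), SAUR20 (-4.25), AT5G18030 (-3.90) and AT4G38840 (-3.80). AT3G22530, annotated only as a heat shock protein, averaged 131 ± 15.0 before heat and was listed at 0 in all heated wild-type libraries at 15 and 90 min. SAUR, HSP20 and HSP70 genes have near-identical relatives, so reads may be split unevenly among them and their values are uncertain gene by gene.

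Every list of heat genes moved up as a whole at 15 min. Of the 13 small heat shock proteins tested 12 rose and none fell (camera adjusted p = 3.2e-26), among them HSP22.0 (8.31), HSP23.6 (8.03) and HSP21 (7.93). Of 25 chaperones and co-chaperones 18 rose (adjusted p = 2.9e-30), with BAG6 (8.07), HSP101 (6.63), HSP70B (6.46) and HSP90.1 (5.27) in front. Of 24 heat shock and related factors 14 rose and 1 fell (adjusted p = 5.3e-13), with HSFA7B (8.14), HSFA2 (7.55), HSFA7A (5.45) and DREB2A (4.76) highest. Among 27 rapidly induced genes 17 rose and 4 fell (adjusted p = 8.1e-15), and the jasmonate repressors JAZ8 (7.03) and JAZ7 (6.25) stood with ZAT10 (6.02) and WRKY40 (5.96). Of 21 genes of the unfolded protein response of the endoplasmic reticulum 5 rose (adjusted p = 7.3e-05, and adjusted p = 0.0647 with an estimated correlation), including ERDJ3A (4.88), NAC062 (3.66) and BZIP28 (1.81). Of 26 immunity genes 11 rose (adjusted p = 9.4e-09, and adjusted p = 0.0847 with an estimated correlation), including WRKY18 (5.59), SARD1 (4.63) and WRKY70 (3.91). Of 11 redox genes 3 rose, APX2 (4.52), RBOHD (3.08) and GOLS1 (2.62) (adjusted p = 0.0132, and adjusted p = 0.173 with an estimated correlation). The counts adjusted over the list alone equalled those over all genes in each of the 19 lists at 15 min and at 90 min.

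The other 12 lists did not move as a whole at 15 min. Of 20 SR splicing proteins SR45A rose (3.16; list adjusted p = 0.161), and of 13 clock genes TOC1 rose (1.61) and RVE1 fell (-1.32; 0.178). No gene passed among 16 splicing factors (0.930; SKIP -0.08, U2AF65A -0.22), 13 NMD factors (0.807), 15 mRNA decay factors (0.307; DCP5 -0.16), 23 cytosolic ribosomal proteins (0.178; RPL3A 0.18), 22 photosynthesis genes (0.856; RCA -0.06) or 9 reference genes (0.657; UBQ10 -0.55). Of 13 known NMD targets only SAC51, a bHLH regulator of stem growth, fell (-1.06, adjusted p = 2.7e-05; list 0.856). Of 17 genes with conserved upstream reading frames 3 rose and 3 fell (0.830), with HSFB1 at 3.60 and BZIP2 at -1.05 (-0.79 without replicate 2 at 15 min), and their median (-0.09) and mean (0.17) differed in sign, the test pointing up. Among 11 root markers WOX5 rose (1.76, from 5.83 to 20.8 counts; list 0.878), and of 10 seed maturation genes AT2S2 (2.61) and AT2S1 (2.56) rose (list 0.930), the latter from 6.17 to 32.8 ± 29.5 counts. Neither passed without replicate 1 of unheated wild type (AT2S2 1.94, adjusted p = 0.155; AT2S1 1.498, adjusted p = 0.215) or without replicate 2 at 15 min (1.90, adjusted p = 0.166; 1.87, adjusted p = 0.138).

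By 90 min the heat genes were among the most abundant transcripts of the seedling. HSP70B averaged 454390 and HSP101 621150 ± 20475 normalized counts, and the 63 genes of the heat lists took 20.4 ± 0.545% of all counts against 0.641 ± 0.0531% before heat. HSP21, a plastid chaperone, showed the largest rise (13.71, SE 0.33, adjusted p = 2.1e-27), ahead of HSP23.6 (12.80), HSP22.0 (12.69), HSP17.6A_CI (11.77), the DnaJ-domain gene AT1G71000 (11.73) and HSP70B (11.65). DIR1, a lipid transfer protein of systemic immunity, averaged 927 ± 63.7 before heat and was listed at 0 at 90 min. EXPA1, an expansin of growing walls, fell from 6310 ± 594 to 104 ± 16.3 (-5.92, SE 0.22, adjusted p = 4.0e-22), and SAUR20 (-6.14), AT1G29460 (-5.72) and the transporter gene AT3G45680 (-5.58) fell with it. Genes that rose numbered 1850, 2379, 2629 and 2523 at 15, 30, 45 and 90 min, and genes that fell 1093, 3490, 4306 and 4890. Of the 1850 that had risen by 15 min 1394 were also called up at 90 min and 48 were called down, and of the 1093 that had fallen 972 were also called down. At every time 1311 genes were called up and 926 down.

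At 90 min small heat shock proteins (12 of 13 up, camera adjusted p = 1.6e-16), chaperones (24 of 25 up, 1.5e-25) and heat shock factors (16 up and 1 down of 24, 6.4e-09) stood high, with BAG6 at 10.65, HSFA7B at 11.61 and HSFA2 at 10.49. Of the unfolded protein response genes 10 rose and 2 fell (0.00022, and adjusted p = 0.0915 with an estimated correlation), and BIP1, an HSP70 of the endoplasmic reticulum, went from 3647 to 39668 counts (3.45). Rapidly induced genes still stood high (19 up, 4 down; 1.1e-07, and adjusted p = 0.0551 with an estimated correlation), with JAZ8 at 6.57 and ZAT12 at 6.54. Of the immunity genes 11 rose and 1 fell (0.0025, and adjusted p = 0.441 with an estimated correlation), among them WRKY18 (6.61) and SARD1 (3.78). Of the SR proteins 6 rose (3.7e-05, and adjusted p = 0.383 with an estimated correlation), including SR45A (5.53), SCL33 (2.27) and SR30 (2.25), and 3 rose and 1 fell under scaling to equal totals. Of the redox genes APX2 (9.80), GOLS1 (6.26) and APX1 (1.73) were among 4 that rose and CSD2 (-2.88) among 2 that fell (0.0475, and adjusted p = 0.369 with an estimated correlation), and under total scaling 2 rose and 2 fell with a median of -0.31 in place of 0.46. Of the genes with upstream reading frames 4 rose and 8 fell (0.375), HSFB1 reaching 6.26 and SACL2, SACL1 and SAC51 -3.21, -2.96 and -2.59. Root markers were mostly lower, 6 down with PYK10 at -2.53 and 1 up, WOX5 at 2.95 (0.267).

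Some group directions at 90 min depended on the scaling. Scaling to equal totals shifted the median of all genes to -0.22, -0.64, -0.85 and -0.90 at 15, 30, 45 and 90 min, against -0.14 at 90 min as deposited, and took the share of calls that were up from 62.9 to 49.6%, 40.5 to 19.4%, 37.9 to 15.0% and 34.0 to 13.1%. The ribosomal protein list (no gene called; test up, 0.0067, and adjusted p = 0.740 with an estimated correlation) had a median of 0.52 as deposited and -0.25 under total scaling, and the photosynthesis list (no gene called, 0.0809) 0.46 and -0.31. Of the 9 reference genes GAPC1 (1.45), UBQ10 (1.31), ACT8 (1.27) and ACT2 (1.17) rose (0.0023, and adjusted p = 0.284 with an estimated correlation), and none of them passed under total scaling. Splicing factors (STA1 up at 1.37; 0.0809) had medians of 0.29 and -0.48. NMD factors (0.969), mRNA decay factors (none called; 0.375) and clock genes (TOC1 1.09, LHY -1.10; 0.663) had 5, 8 and 6 genes down under total scaling. Without replicate 2 of unheated wild type TOC1 (0.99) and LHY (-0.87), and without replicate 1 LHY (-0.96), were below 2-fold. Of the known NMD targets 3 rose and 3 fell (0.762), and of the seed genes none passed (0.931; CRA1 -2.52, adjusted p = 0.0780). For NMD targets and clock genes the medians (-0.11 and -0.07) and means (-0.04 and -0.02) were below 0 while the test pointed up, and under median-of-ratios scaling the medians were 0.01 and 0.05. With an estimated correlation the calls of small heat shock proteins, chaperones and heat shock factors held at 15 min (adjusted p = 0.0028, 0.0028 and 4.7e-05) and at 90 min (adjusted p = 0.0206, 0.0110 and 0.00082), and that of rapidly induced genes at 15 min (adjusted p = 0.0028).

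**Figure D2:**
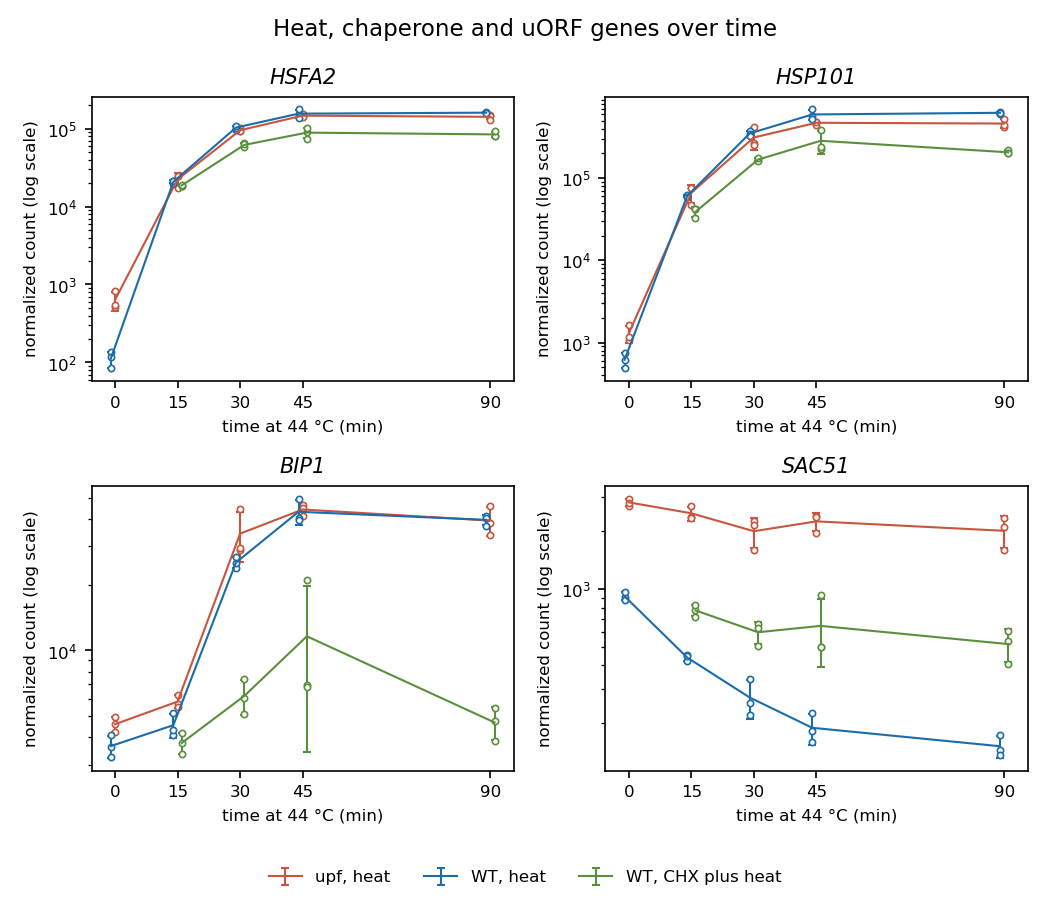
Normalized counts on log axes (vertical) of the heat shock factor HSFA2, the chaperones HSP101 and BIP1 and the bHLH gene SAC51 against minutes at 44 °C (horizontal) in upf, wild type and wild type with CHX; points are libraries, lines join means and bars are ± SD (n = 3). SAC51 ended at 152 in wild type, 516 with CHX and 2006 in upf at 90 min, and BIP1 at 39668, 4681 and 39362.

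The same heat series in upf asks whether seedlings short of NMD respond alike. In upf 1667, 2218, 2371 and 2274 genes rose and 965, 2832, 3674 and 4173 fell at 15, 30, 45 and 90 min, and 1295 were up and 796 down at every time. Under total scaling the median of all genes in upf was -0.76 at 90 min, and the share of calls that were up went from 63.3 to 47.2%, 43.9 to 19.4%, 39.2 to 16.2% and 35.3 to 14.8%. HSFA2 reached 141210.0 ± 9891 normalized counts in upf at 90 min against 159650.0 ± 2109 in wild type, and HSP101 459730.0 ± 57215 against 621150.0 ± 20475. The difference of the heat responses was tested as an interaction and passed for 13, 220, 459 and 492 genes at 15, 30, 45 and 90 min. At 15 min 23.1% of the calls were higher in upf, and 0% under total scaling. At 90 min 395 of these were higher in the upf response, including the uncharacterized AT5G02670 (3.33, SE 0.30, adjusted p = 7.6e-09), the auxin response repressor IAA4 (2.88) and the kinase gene AT1G49180 (2.67). The 97 lower ones included PR1, a marker of salicylic acid signalling (-6.23, SE 1.42, adjusted p = 0.0069), AT5G18065, a target of trans-acting siRNA (-2.73), and HSFA2 (-2.66, SE 0.23, adjusted p = 2.8e-09). PR1 and HSFA2 already stood higher in upf before heat, PR1 with a wide spread (values below). Against wild type HSFA2 was at 2.48 before heat and at -0.18 at 90 min.

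Of the lists, chaperones (0 up and 4 down, camera adjusted p = 2.8e-10, and adjusted p = 0.195 with an estimated correlation) and heat shock factors (0 up and 3 down, 0.00024, and adjusted p = 0.0699 with an estimated correlation) had the lower response in upf, with HSP70B at -1.87 and HSFA1E at -1.74. Under total scaling 2 chaperones were called down, with the factors at 3 as before. Genes with upstream reading frames went the other way, 6 higher or 7 adjusted over the list alone (2.2e-05, and adjusted p = 0.0872 with an estimated correlation), including SAC51 (2.08), SACL1 (2.00) and BZIP2 (1.62). Rapidly induced genes had 4 higher or 5 adjusted over the list alone (0.0028, and adjusted p = 0.391 with an estimated correlation), of which IAA4, IAA3 (2.00) and IAA2 (1.47) respond to auxin. Immunity genes had 4 lower (0.0062, and adjusted p = 0.497 with an estimated correlation), namely PR1, FRK1 (-3.04), WRKY70 (-1.41) and EDS5 (-1.24). SR proteins had SR45A lower (-1.42; 2.2e-05, and adjusted p = 0.391 with an estimated correlation), and small heat shock proteins had HSP21 lower (-1.73) and HSP15.4 higher (1.32; 0.0217, and adjusted p = 0.518 with an estimated correlation). The unfolded protein response (0.0217, and adjusted p = 0.391 with an estimated correlation), splicing factor (0.0217, and adjusted p = 0.497 with an estimated correlation), ribosomal (0.00024, and adjusted p = 0.507 with an estimated correlation) and reference lists (0.0282, and adjusted p = 0.497 with an estimated correlation) had no gene past limma's test. Root markers had none, or 1 lower adjusted over the list alone (0.0109, and adjusted p = 0.391 with an estimated correlation). ERF1-1 was the NMD factor that was higher (1.21; 0.935) and APX2 the redox gene that was lower (-1.13; 0.154). Known NMD targets had SAC51 higher (0.498), and mRNA decay factors (0.3004), photosynthesis (0.0822), clock (0.188) and seed genes (0.458) had none. The calls of FRK1, HSP15.4, HSP21, EDS5, APX2 and WRKY70 ended without 9, 8, 6, 6, 5 and 4 of the 12 libraries left out in turn. At their highest p they were -2.63 for FRK1 (adjusted p = 0.165), 1.01 for HSP15.4 (adjusted p = 0.153) and -0.75 for EDS5 (adjusted p = 0.140) without replicate 1 of unheated upf. They were -1.204 for HSP21 (adjusted p = 0.160) and -1.11 for WRKY70 (adjusted p = 0.0787) without replicates 2 and 3 of unheated wild type. APX2 stood at -0.92 (adjusted p = 0.121) without upf replicate 3 at 90 min. FRK1 did not pass under median-of-ratios (adjusted p = 0.0513) or total scaling (adjusted p = 0.0616) either.

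Comparing upf with wild type at each time asks which transcripts stand higher when NMD is impaired. Most of the called genes were higher in upf: 1242 up and 307 down before heat, then 1304 and 285, 1698 and 333, 1745 and 409, and 1830 and 412 at 15, 30, 45 and 90 min. At every time 684 were up and 42 down, and for the mean over the times 1558 were up and 223 down. Total scaling shifted the median of all genes to 0.10 and 0.15 at 45 and 90 min. The largest mean increases were of MRD1 (log2 change 7.80, SE 0.39, adjusted p = 1.8e-18), AT3G60950, annotated with a C2 domain (7.20), PR1 (6.93), the iron-deficiency bHLH factors BHLH100 (5.89) and bHLH38 (5.80), and the uncharacterized AT5G26970 (5.75). MRD1 averaged 414 counts in upf and 1.1 in wild type over the times. PR1 varied widely within upf, at 2223 ± 1916 before heat against 2.5 ± 1.5 in wild type. The largest decreases were of IPS1, a non-coding RNA induced by phosphate starvation (-3.58), the purple acid phosphatase PAP14 (-3.52), MLP328 (-2.99, from 2725 to 330), the galactolipid synthase MGDC (-2.98), PEPC1 (-2.79) and the methyltransferase gene AT5G37990 (-2.54).

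Known targets of NMD were higher in upf. Of 13 tested, 5 rose before heat and none fell (camera adjusted p = 1.9e-08), and likewise 5 for the mean (6.5e-06, and adjusted p = 0.115 with an estimated correlation). Among them were the kinase gene AT5G45430 (2.19, SE 0.19, adjusted p = 5.0e-10; 17683 ± 1032 against 3875 ± 235), the initiation factor gene AT1G36730 (1.89), TFIIIA, a 5S rRNA transcription factor (1.88; 1842 ± 239 against 498 ± 43.1) and SAC51 (1.62; 2822 ± 121 against 916 ± 44.9). The remaining members did not pass before heat, with BTZ at 0.63, PTB1 at 0.61, MHX at 0.48, PTB2 at 0.37, RS2Z33 at 0.16, SR30 and GRP7 at -0.16 and GRP8 at -0.09. Of 17 genes with conserved upstream reading frames 6 rose before heat (1.7e-06) and 8 for the mean (1.2e-07), including the methyltransferase NMT1 (2.59, from 426 to 2572 counts), SAMDC2 of polyamine synthesis (2.04) and, for the mean, SACL1 (2.43) and SACL3 (2.23). The 13 NMD factors did not pass as a list (0.751; mean 0.554, with a median of -0.19 and a mean of 0.06): the release factor ERF1-1 rose (2.07, SE 0.17, adjusted p = 5.4e-11; 2791 ± 233 against 663 ± 17.62), and UPF1 and UPF3 fell. With an estimated correlation the calls of the NMD targets and the upstream reading frame genes held before heat (adjusted p = 0.0430 for each), and that of the latter for the mean (adjusted p = 0.0349).

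Immunity genes were also higher in upf: 11 of 26 rose before heat, or 12 adjusted over the list alone (1.7e-06, and adjusted p = 0.339 with an estimated correlation), and 10 for the mean (0.00035, and adjusted p = 0.791 with an estimated correlation). They included PR1 (9.08 before heat, SE 1.00, adjusted p = 3.0e-08), NUDT6 (4.02), WRKY38 (3.65) and SARD1 (3.54). Seed maturation genes rose as well, 5 of 10 before heat or 7 adjusted over the list alone (0.0051, and adjusted p = 0.670 with an estimated correlation) and 7 for the mean (0.0138, and adjusted p = 0.860 with an estimated correlation), with AT2S2 at 3.61, the oleosin OLEO1 at 3.58 and, for the mean, the storage proteins CRC at 3.69 and CRA1 at 2.96. Their spread within groups was wide, OLEO1 averaging 361 ± 85.9 in upf and 54.3 ± 66.0 in wild type. Without wild-type replicate 1 OLEO1 (2.54, adjusted p = 0.0926), OLEO2 (1.77, adjusted p = 0.274) and EM1 (1.63, adjusted p = 0.145) did not pass before heat. Nor did EM1 without upf replicate 1 (1.80, adjusted p = 0.121). For OLEO2 5 single libraries ended the call. Before heat some heat genes already stood higher in upf: 2 heat shock factors, or 3 adjusted over the list alone (0.153), led by HSFA2 (2.48, SE 0.16, adjusted p = 1.2e-12; 632 ± 178 against 112 ± 26.0) and HSFA1E (2.23). Likewise 3 chaperones rose (0.0223, and adjusted p = 0.764 with an estimated correlation), HSP70B (1.60), HSP101 (1.06) and HSP70-2 (1.04). HSP101 was below 2-fold without upf replicate 3 (0.87) or wild-type replicate 1 (0.90). HSP70-2 was so without upf replicate 1 (0.86) or wild-type replicates 1 (0.90) or 3 (0.99). Of the small heat shock proteins HSP21 (1.37) and HSP22.0 (1.07), at 1.5 and 5.83 counts in wild type, rose and HSP15.4 fell (-1.25; 0.331). HSP21 and HSP22.0 did not pass without upf replicate 3 (0.85, adjusted p = 0.0749; 0.35, adjusted p = 0.463) or wild-type replicate 2 (0.84, adjusted p = 0.0799; 0.87, adjusted p = 0.144). Nor did HSP22.0 without wild-type replicate 1 (0.78, adjusted p = 0.165). HSP15.4 was below 2-fold without upf replicate 1 (-0.94). For the mean these lists had 1 (HSFA1E, 1.15; 0.871), 0 (0.370) and 0 (0.981) genes past limma's test.

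The remaining lists moved little between the genotypes. SR proteins RS40 (1.59) and SR45A (1.01; 0.97 without upf replicate 3 and 0.93 without wild-type replicate 1) rose before heat (0.0016, and adjusted p = 0.672 with an estimated correlation), with 1 called under median-of-ratios scaling and 3 under total scaling, and RS40 for the mean (1.65; 0.271). NAC103 of the unfolded protein response rose (1.298; 0.143; mean 1.78, 0.514). Rapidly induced genes had 1 up (IAA3, 1.21) and 2 down (IAA6 -2.12, JAZ5 -1.23) before heat (0.0221, and adjusted p = 0.670 with an estimated correlation) and 2 up and 1 down for the mean (0.507), and IRT1 was the root marker that rose for the mean (1.08, adjusted p = 0.036; list 0.698 before heat, 0.514 mean). That call ended without 15 of 30 libraries left out in turn (0.82, adjusted p = 0.0872 without replicate 3 of unheated wild type). Photosynthesis genes had none past limma's test and tested lower both before heat (0.0030, and adjusted p = 0.764 with an estimated correlation) and for the mean (0.00039, and adjusted p = 0.860 with an estimated correlation), and ribosomal genes for the mean (0.0229, and adjusted p = 0.860 with an estimated correlation; 0.709 before heat). No gene passed limma's test among splicing factors (0.610; mean 0.316), mRNA decay factors (0.447; mean 0.320), clock (0.429; mean 0.871), redox (0.767; mean 0.759) and reference genes (0.331; mean 0.0964). The medians of chaperones, heat shock factors and clock genes for the mean were -0.07, -0.07 and -0.08 as deposited and 0.04, 0.05 and 0.04 under total scaling.

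Transcript usage asks which splice forms build up without NMD. The usage log2 change is a transcript's log2 change against that of its gene's other transcripts. It is not a fold of the transcript's share of the gene's total, which is given in percent beside it. Of the SR protein genes RS41 shifted in upf to AT5G52040.4 (chromosome 5, 21130320 to 21133551, plus strand), which took 35.1 ± 3.47% of the gene's total over the times against 4.49 ± 1.79% in wild type (usage log2 change 4.73), and away from AT5G52040.2 (0.781% against 26.7%, -7.38). SR34A shifted to AT3G49430.7 (52.0 ± 8.72% against 4.23 ± 2.18%) and RS40 to AT4G25500.3 (73.9 ± 4.41% against 21.9 ± 5.73%). Among all genes the largest gains were of SEC1A transcript AT1G02010.1, of the vesicle fusion machinery (72.6 ± 9.09% against 12.4 ± 14.2%), the cysteine desulfurase NFS1 transcript AT5G65720.2 (10.6% against 0.505%), AT4G24920.2 (32.5 ± 16.4% against 2.04%), the nitrate regulator NLP7 transcript AT4G24020.2 (13.7% against 1.77%) and ABCI15 transcript AT3G20320.2 (chromosome 3, 7087445 to 7089927, minus strand; 52.5 ± 3.05% against 5.46 ± 4.73%). AT1G61430.6 was listed at 0 in upf and took 19.8% in wild type. Before heat 262 transcripts rose and 216 fell in usage, in 313 genes, and for the mean 1618 and 1519, in 1667 genes. Of 68 SR transcripts 11 rose and 17 fell for the mean, in 9 of 16 genes, beside 3137 called of all 22958 transcripts, of 33 splicing factor transcripts 4 and 4, of 22 NMD factor transcripts 3 and 3, and of 24 heat shock factor transcripts none passed limma's diffSplice. Calls before heat leaned on single libraries: 252 passed without upf replicate 1 and 296 without wild-type replicate 2, against 478. The authors' deposited table gives log2 changes of transcript level, not of usage, in unheated upf. They are 3.14 (adjusted p = 7.7e-57) for AT5G52040.4, 3.29 for AT4G25500.3, 3.91 for AT3G49430.7, 2.97 for AT3G20320.2 and 3.09 for AT1G02010.1.

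Usage in wild type heated without CHX differed widely from that at 0 min. At 15, 30, 45 and 90 min 756, 3315, 3955 and 3834 transcripts passed, in 474, 1859, 2197 and 2163 genes. At 30 min the inositol phosphate synthase MIPS2 lost its transcript AT2G22240.1, which went from 99.5 ± 0.515% to 6.98 ± 4.35% of the gene's total (usage log2 change -11.87). The counts of AT5G57950 were assigned wholly to AT5G57950.2 (100% against 13.5 ± 13.02%) with AT5G57950.1 listed at 0. These 2 transcripts have 5 exons each and the same end. They start at 23460673 and 23460696 and are 1036 and 1013 nt long. Few reads can tell them apart, so this split is uncertain. AT3G61320.2 took 91.6 ± 3.17% against 1.47%. The kinase gene FC2 gained AT4G24740.5 (10.7%), listed at 0 before heat, and lost AT4G24740.1, listed at 0 at 30 min. The calreticulin CRT1A transcript AT1G56340.1 went from 73.8 to 99.5%. At 90 min 11 SR transcripts rose and 11 fell, in 10 of 16 genes, as did 8 and 5 of the splicing factors, 3 and 2 of the NMD factors and 5 and 6 of the heat shock factors.

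A stop codon more than 50 nt before the last exon junction is a textbook mark of an NMD target, and 3245 of the 48147 transcripts with a coding sequence have one in the TAIR10.1 annotation. Transcripts with such a stop made up 16.2% (262 of 1618) of those raised in usage in upf for the mean and 12.4% (188 of 1519) of those lowered, against 9.64% of those not called. The odds ratio of raised against lowered was 1.37 (95% interval 1.11 to 1.68; Fisher's exact test, 2-sided, adjusted p = 0.0057), and 1.19 (adjusted p = 0.187) for stops over 100 nt before the junction. By time it was 1.16, 1.48, 1.24, 1.97 and 1.498 at 0, 15, 30, 45 and 90 min, past 0.05 at 45 (adjusted p = 0.0002) and 90 min (adjusted p = 0.0181). For stops over 100 nt before the junction it was 0.968 at 0 min, 1.98 (adjusted p = 0.00032) at 45 min and 1.28 (adjusted p = 0.221) at 90 min. Heat in wild type likewise raised such transcripts at 30 (16.4% against 9.73%, odds ratio 1.81), 45 (1.57) and 90 min (1.35), with 0.851 at 15 min. With CHX 11.7% of raised and 15.9% of lowered transcripts for the mean had such a stop, against 9.56% of those not called (odds ratio 0.701, adjusted p = 0.00061), with 0.528, 0.635, 0.826 and 0.718 at 15, 30, 45 and 90 min. Of 13 named transcripts raised in upf 3 have such a stop, AT3G20320.2 215 nt, AT5G47880.1 of ERF1-1 130 nt and AT4G24920.2 74 nt before the last junction, while AT1G61430.6, lowered in upf, has it 287 nt before.

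**Figure D3:**
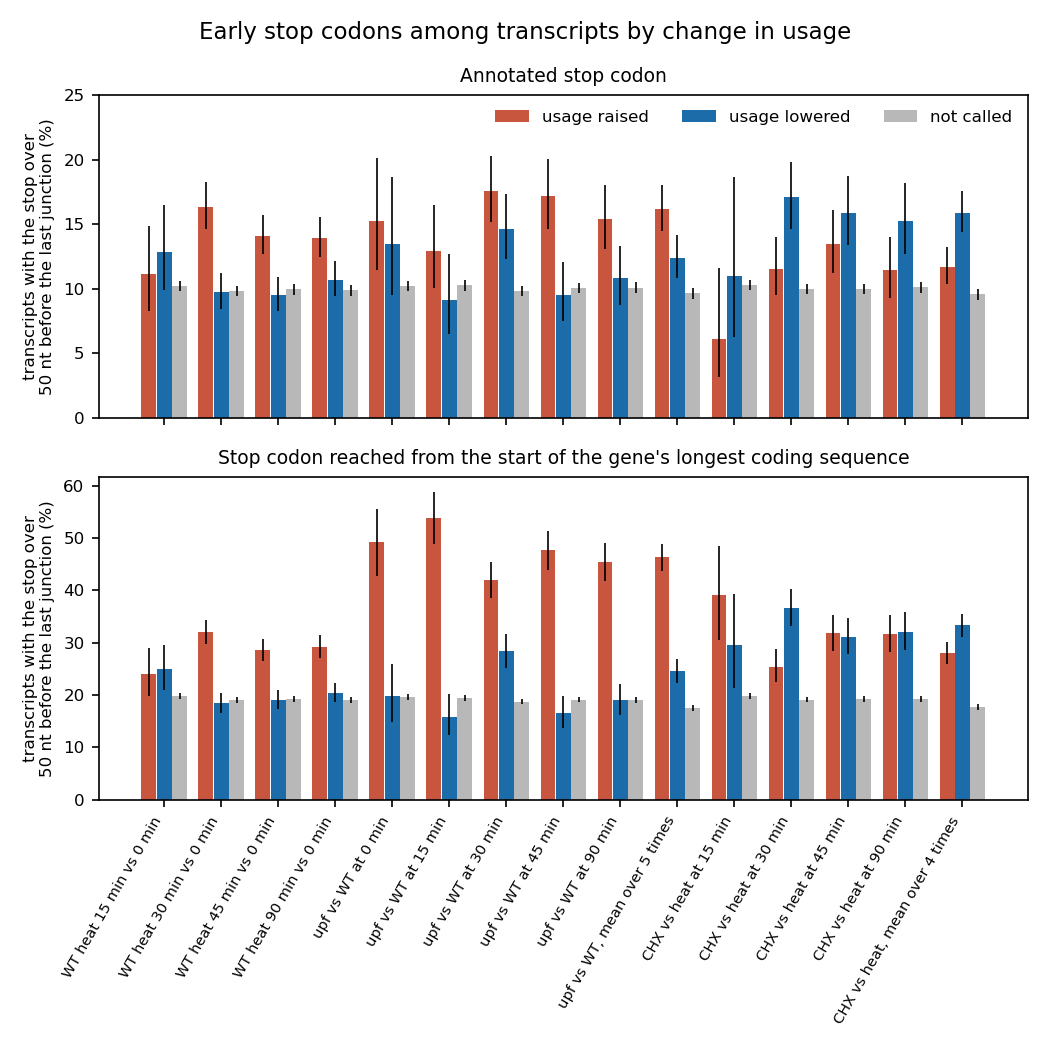
Percent of transcripts with a stop codon over 50 nt before the last junction (vertical axes) among those raised, lowered or not called in usage in each comparison (horizontal axis), with the annotated stop above and the stop read from the start of the gene's longest coding sequence below; bars start at 0 and lines are Wilson 95% intervals. For upf the mean over 5 times gave 16.2% raised and 12.4% lowered with the annotated stop, and 46.3% and 24.6% with the other.

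Heat with CHX against heat alone asks which transcripts change when translation, on which NMD depends, is inhibited. Most called genes were higher with CHX: 880 up and 102 down at 15 min, then 2612 and 506, 2514 and 514, and 2799 and 574, with 571 up and 28 down at every time and 1939 up and 287 down for the mean over the 4 times. Scaling to equal totals shifted the median of all genes to 0.11, 0.32, 0.39 and 0.51, against 0.08 at 90 min as deposited, and the share of calls that were up from 83.8 to 93.9%, 83.0 to 95.7% and 83.0 to 96.9% at 30, 45 and 90 min. CBF2, a cold-response AP2/ERF factor, averaged 2329 counts with CHX and 126 without (log2 change 4.29, SE 0.15, adjusted p = 7.2e-22), the jasmonate-linked factor ORA47 2758 and 155.7 (4.38), and SAUR24 148 and 4.75 (4.76). AT4G02720 (5.82) and the SAUR-like AT1G29450 (4.39) and AT1G29430 (4.25) were likewise raised. The largest decreases were of AT1G51090, with a heavy metal domain (-3.59, from 712 to 75.9), RAP2.9 (-3.51), AT1G30060 (-2.86), the subtilase AT4G21323 (-2.71), AT5G62360, a pectin methylesterase inhibitor (-2.59), and the AP2/ERF factor ABR1 (-2.58).

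Of 27 rapidly induced genes 19 rose and none fell for the mean CHX effect (camera adjusted p = 4.3e-13, and adjusted p = 0.0203 with an estimated correlation), 21 rising under total scaling. CBF1 (4.08), ERF5 (3.81) and IAA1 (3.32) followed CBF2. Chaperones went the other way, 7 of 25 down (3.7e-14, and adjusted p = 0.117 with an estimated correlation), with 1 down under total scaling and 9 under median-of-ratios scaling. HSP101 averaged 173990 with CHX and 405740 without (-1.10), and HSP70B (-1.30), ROF2 (-1.19) and MTHSC70-2 (-1.12) fell too. Of the small heat shock proteins HSP17.4_CIII fell (-1.15; 2.3e-05, and adjusted p = 0.347 with an estimated correlation), none passing under total scaling, and at 90 min 10 were down or 5 under total scaling. The unfolded protein response had 5 of 21 down (0.00074, and adjusted p = 0.238 with an estimated correlation), or 4 down and 2 up under total scaling, with BIP2 at 3344 against 16582 counts (-2.11), BIP1 (-1.88), CNX1 (-1.44) and P58IPK (-1.31). At 90 min 18 chaperones were down (3.4e-16, and adjusted p = 0.0493 with an estimated correlation) or 7 under total scaling, and 9 unfolded protein response genes (8.1e-06, and adjusted p = 0.0493 with an estimated correlation) or 8. Of the heat shock factors HSFA6A (2.33), HSFA6B (2.32), HSFC1 (2.13) and HSFA8 (2.12) were among those up and none was down. The list did not pass (0.787). Their median was -0.01, or 0.27 under total scaling, while their mean was 0.33 and the test pointed up.

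Among the NMD lists with CHX, TFIIIA (1.79, 748 against 221 counts) and SAC51 (1.35, 631 against 263) rose of the 13 targets (0.540), with AT5G45430 at 0.92 and AT1G36730 at 0.13. Among the NMD factors ERF1-1 (1.27) rose (0.540), as did 6 genes with upstream reading frames (0.161), led by SACL2 (1.98), SACL1 (1.85) and BZIP1 (1.56), and 6 immunity genes (0.105), led by CBP60G (2.68), SARD1 (2.44) and WRKY70 (2.40). Root markers PLT2 (1.16) and SHR (1.04) rose and WOX5 fell (-1.15; 0.540). The SR (0.0050, and adjusted p = 0.636 with an estimated correlation), splicing factor (0.0368, and adjusted p = 0.636 with an estimated correlation), ribosomal (0.00074, and adjusted p = 0.636 with an estimated correlation), photosynthesis (0.00052, and adjusted p = 0.636 with an estimated correlation) and reference lists (0.00074, and adjusted p = 0.287 with an estimated correlation) tested lower with no gene past limma's test, and their medians of -0.17, -0.11, -0.28, -0.39 and -0.42 became 0.11, 0.17, 0.00, -0.10 and -0.13 under total scaling. Redox (0.136), clock (0.597), mRNA decay (0.632) and seed genes (0.911) had none, the seed list having a median of 0.14 and a mean of 0.18 while the test pointed down. In usage 231, 1570, 1480 and 1364 transcripts passed at 15, 30, 45 and 90 min and 3882 for the mean, in 2183 genes. BTB gene BPM2 transcript AT3G06190.4 (9.99% against 1.05%; stop 225 nt before the last junction), AT1G02010.1 of SEC1A (55.2% against 8.64%), AT5G13590.1 (36.3% against 10.13%) and AT1G04970.2 (23.0% against 2.65%) gained most, and AT1G03290.3 (0.597% against 39.2%), AT4G24740.5 of FC2 (0.0960% against 9.61%), AT1G60200.3 (1.74% against 14.4%) and the polyubiquitin UBQ14 transcript AT4G02890.3 (0.923% against 13.9%) lost most. Of the SR transcripts 11 rose and 13 fell, in 10 genes. Usage counts with CHX leaned on single libraries, going as low as 93 at 15 min without wild-type replicate 1, 1000 at 30 min without CHX replicate 1, 859 at 45 min without wild-type replicate 2 and 838 at 90 min without CHX replicate 3.

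Setting the CHX effect beside the effect of upf before heat, which share no library, asks whether the inhibitor and the mutant raise like transcripts. Transcripts raised in usage by both numbered 34, 68, 89 and 78 at 15, 30, 45 and 90 min of CHX, against 1.495, 8.89, 8.55 and 8.08 expected of independent lists (odds ratios 34.7, 10.8, 17.2 and 14.8). Those lowered by both numbered 23, 47, 64 and 54 against 0.941, 7.44, 6.88 and 6.17. Genes raised by both numbered 91, 269, 427 and 378, against 52.7, 156.4, 150.5 and 168 (odds ratios 1.88, 2.03, 4.37 and 3.09; Fisher's exact test, 2-sided, p = 2.9e-07, 3.9e-20, 1.8e-100 and 3.9e-58). Genes lowered by both were few, 1, 9, 18 and 8 against 1.51, 7.49, 7.61 and 8.49. Across genes, which are not independent replicates, the effects correlated with r of 0.036, 0.056, 0.228 and 0.129, and across transcripts in usage with 0.251, 0.258, 0.269 and 0.231. Against the effect of upf at the same time, which shares the heated wild type, r was 0.156, 0.293, 0.395 and 0.312 across genes with covariances of 0.0533, 0.166, 0.229 and 0.185, where unchanged groups simulated against a shared control gave 0.505 and 0.0376. In usage r was 0.581, 0.635, 0.512 and 0.527 with covariances of 0.852, 1.37, 1.03 and 1.1035, against 0.501 and 0.446 simulated. In those same-time comparisons 126, 517, 725 and 698 genes were raised by both, against 55.3, 214, 211 and 247 expected of independent lists and 0 simulated, and part of the excess may come from the shared libraries.

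The authors' deposited tables list tests per transcript for these comparisons. For unheated upf against wild type the authors' deposited table has 2254 transcripts up and 843 down. Of the 2910 of these that could be compared, 1833 were also called here among 1939, none in the opposite direction. For wild type at 90 min the authors' deposited table calls 11721 compared transcripts, of which 10792 were also called here among 11508. For CHX at 90 min the authors' deposited table calls 5905, of which 4833 were also called here among 5154. No transcript called in both went opposite ways in any comparison.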

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

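The tests of scaling, of a stressed unheated library and of the level before heat on the heat lists, of a varying seed source, of shared libraries and of scaling in the CHX comparison, and the second kind of split below were chosen only after the result was seen. The results in this part stand out because the heat response differed between upf and wild type by a test of the difference itself, or because a gene list moved in a way that the comparisons above did not set out to test.

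The heat response differed for 13, 220, 459 and 492 genes at 15, 30, 45 and 90 min. When genotype labels were exchanged within times, 16, 15, 12 and 14 of 100 splits called at least as many genes, up to 2187, 2592, 4415 and 4422, with medians of 0, so these splits do not exclude chance. Splits that call several times the real count point to a structure of the samples, since a full exchange of labels at 1 time turns the genotype difference into a response difference. Splits that exchanged the libraries' deviations from an additive fit of genotype and time instead gave the real count as the highest, 1 of 100 at each time. The highest others were 12, 29, 23 and 31. Since that kind of split was chosen after the other had been seen, it does not settle the question.

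Of the heat lists, 4 of 25 chaperones and 3 of 24 heat factors rose less to 90 min in upf than in wild type, HSFA2 (-2.66), HSP70B (-1.87), HSFA1E (-1.74), HSFA7B (-1.53), HSP101 (-1.50), BAG6 (-1.17) and HSA32 (-1.02), and none rose more, while of 13 small heat shock proteins HSP21 (-1.73) rose less and HSP15.4 (1.32) more; the calls of BAG6, HSA32, HSP21 and HSP15.4 ended without 7, 4, 6 and 8 of 12 libraries left out in turn (at their nearest to 0 -0.85, -0.91, -1.204 and 1.01, without unheated upf replicate 3, unheated wild-type replicates 3 and 2 and unheated upf replicate 1), and with an estimated correlation camera called none of the 3 lists (adjusted p = 0.195, 0.0699 and 0.518). Over all 62 members, called or not, the mean less the median of all genes had a response difference of -0.56 (95% t interval over libraries -0.82 to -0.29; 52 of 62 below 0), which 1 scaling factor per library cannot give. A single stressed unheated upf library does not account for all of it, since it was -0.42 (-0.67 to -0.18) or lower without each of the 3. Over the 62 members a higher level before heat in upf (0.24, 0.05 to 0.43) made up part of it, with a lower level at 90 min as the rest (-0.32, -0.51 to -0.13), while of the called genes, which were picked for the difference, HSFA2, HSP70B and HSFA1E stood 2.48, 1.60 and 2.23 above wild type before heat and at -0.18, -0.27 and 0.49 at 90 min, so how much it accounts for stays open. Whether upf seedlings were primed or had met a stress before heat was not tested.

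Seed maturation transcripts were higher in upf, by a mean log2 difference of 2.09 over the 5 times. With an estimated correlation camera did not call this list before heat or for the mean. They did not rest on 1 library, since the difference stayed at 1.90 or above without each of the 30 libraries in turn. The members' deviations from their group means went together (mean pairwise correlation 0.562, against a 95th percentile of 0.0749 and a highest value of 0.212 in 836 random lists of like level). The random lists were matched on level alone, and genes regulated together would exceed them too. This test therefore cannot tell a varying amount of some seed source in the material from regulation. The cruciferin CRA1 reached 5930 counts in replicate 3 of unheated wild type, so high values were not confined to upf. Whether upf seedlings kept seed transcripts for longer or more seeds had failed to germinate was not tested.

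The CHX effect ran against the heat effect at 30, 45 and 90 min: across genes, in 6 pairs of times without a shared library, r lay between -0.480 and -0.374, and genes lowered by heat stood 0.963 to 1.28 above genes raised by heat in their median CHX effect. Since no library is shared in these pairs and 1 factor per library moves all genes alike, neither shared libraries (highest r -0.352 without each library in turn) nor scaling (smallest difference 0.895) accounts for them. In the 6 pairs with 15 min, set apart after weaker values had been seen there, r ran from -0.318 to -0.0693 and the difference from 0.315 to 0.900, and without each library in turn r reached -0.0425 and the difference 0.293 at their nearest to 0, so shared libraries and scaling do not account for these either. The pattern is mixed: of genes called at 15 min of heat, 555 lowered and 529 raised by heat were raised by CHX at 30 min, against 137.6 and 232.9 expected of independent lists, and among the later pairs genes raised by heat were raised by CHX above that number in 3 of 6 (heat at 30 and CHX at 90 min 341 against 321, 45 and 30 min 381 against 331, 90 and 30 min 372 against 318). A biological explanation, that CHX may slow the heat response, stays untested, since no unheated CHX group was analysed here.

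The other response differences at 90 min are given as values. The higher ones were AT5G02670 (3.33), AT4G09435 of the TIR-NBS-LRR class (2.98), IAA4 (2.88), AT5G45460 (2.86), the F-box gene AT3G18320 (2.83) and the kinase gene AT1G49180 (2.67). Among the list members, SAC51 (2.08), SACL1 (2.00), BZIP2 (1.62) and SACL3 (1.52) have upstream reading frames, IAA3 (2.00), TCH4 (1.52) and IAA2 (1.47) are rapidly induced, and HSP15.4 (1.32) and ERF1-1 (1.21) were higher as well. The lower ones were PR1 (-6.23), FRK1 (-3.04), AT5G18065 (-2.73), the carbohydrate kinase gene AT1G50390 (-2.50), DAR6 (-2.29), CML41 (-2.19), SR45A (-1.42), WRKY70 (-1.41), EDS5 (-1.24) and APX2 (-1.13).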

How the results depend on the processing

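The draws of replicate numbers and the alternatives of leaving out the libraries that stand apart, of 84 separate lanes and of the stop read from the longest coding sequence were chosen only after the data were seen. Of the summary results, 676 values under planned and 65 under added alternatives kept their direction and side of the threshold or stayed within 1.5 times. For the named genes 8716 alternative values were like the reported ones, 150 lost the threshold, 6 gained it and 124 moved. For the named transcripts 1104 were alike and 1 lost it. Many of these genes and transcripts were picked for large changes in these data, and a gene that stayed uncalled counts as alike. The high numbers alike were therefore partly set by the choice and do not measure robustness. IRT1 for the upf mean and the FRK1 response difference each lost the threshold in 16 settings, and the response differences of BAG6, HSP15.4, HSP21, EDS5, APX2, WRKY70 and HSA32 in 11, 10, 8, 8, 6, 5 and 5. A test of counts was not possible, a fit without the trend does not apply to diffSplice, and transcripts as deposited give no value for a named gene, so these were not run. The labels do not say that the replicate number pairs samples, and single pairs of the same number ran from r = -0.395 to 0.490, but the number carried a weak shared effect: mean r was 0.0431 between libraries of the same number and -0.0214 otherwise (10000 draws of the numbers within groups, p = 0.0047), 22 of 42 libraries were closest on average to their own number against a median of 14 in the draws (p = 0.0452), and replicate 1 held more plastid-encoded counts than replicate 3 in 13 of 14 groups (exact binomial test, 2-sided, p = 0.00183). As a block it called 2949 genes for wild type at 15 min against 2943 and moved no count by over 1.5 times. In simulated data 47.8% of 2-fold gene changes, which lie at the fold threshold, were called, and 86.6% passed by adjusted p alone. Of 4-fold usage changes 26.9% were called, so a usage change that is not called may still be large.

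Counts that moved by over 1.5 times are given with the reported count; where no reason is stated the cause was not tested. Total scaling called more genes, since it shifts all genes one way: 10793 (6935) and 11139 (7413) in wild type at 45 and 90 min, 8043 (5050), 9605 (6045) and 9808 (6447) in upf at 30, 45 and 90 min, 5459 (3373) for CHX at 90 min and 3467 (2226) for its mean. Transcripts as deposited, more items than genes, gave 9252, 11157 and 11508 in wild type at 30, 45 and 90 min, 9100 in upf at 45 min, 3360, 3265, 3426 and 4044 for upf against wild type at 30, 45 and 90 min and the mean, and 4980, 4800, 5154 and 5480 for CHX at 30, 45 and 90 min and the mean. In usage, a pseudocount of 5 gave 745 (478) for unheated upf, the filter of at least 50, which tests fewer transcripts, 1917 (3137) for the upf mean and 2513 (3882) for the CHX mean, and the log2 ratio 145 (231) for CHX at 15 min. With only the compared libraries usage calls were 1030 (478), 768 (1635), 870 (1380) and 807 (1512) for upf at 0, 30, 45 and 90 min and 512 (1480) and 788 (1364) for CHX at 45 and 90 min, and the response difference at 30 min 145 genes (220). Without the libraries that stand apart the response difference at 15 min was 28 (13) and CHX usage at 15 min 441 (231). Treating lanes as libraries, which are not replicates, gave response differences of 158, 563, 930 and 999.

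Leaving out 1 library gave ranges of 252 to 449 for usage in unheated upf (252 without upf replicate 1, 296 without wild-type replicate 2), 455 to 742 at 15 min (455 and 483 without upf replicates 3 and 1, 503 without wild-type replicate 1) and 993 to 1921 at 30 min (993 without upf replicate 3). For CHX usage they were 93 to 297 at 15 min (93 and 134 without wild-type replicates 1 and 3, 110 and 108 without CHX replicates 1 and 3), 1000 to 1316 at 30 min (1000 without CHX replicate 1, 1018 without wild-type replicate 1), 859 to 2039 at 45 min (859 and 967 without wild-type replicates 2 and 1, 902 and 938 without CHX replicates 1 and 3) and 838 to 1503 at 90 min (838 without CHX replicate 3). The response difference at 15 min ran from 10 to 20 genes (20 without wild-type replicate 3 at 0 min). Gene counts ran from 2830 to 2945 and 7260 to 7550 in wild type at 15 and 90 min, 1320 to 1570 in unheated upf, 1755 to 1807 for the upf mean, 2183 to 2330 for the CHX mean and 370 to 528 for the response difference at 90 min.

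Odds ratios of early stops over 100 nt before the junction were 0.968 (upf at 0 min), 1.28 (90 min, adjusted p = 0.221), 1.19 (mean, adjusted p = 0.187) and 0.628 (CHX at 90 min, adjusted p = 0.0175). Read from the longest coding sequence they were 3.90, 6.15 and 1.83 for upf at 0, 15 and 30 min, and 1.53 (adjusted p = 0.232) and 1.03 (adjusted p = 0.856) for CHX at 15 and 45 min. For genes lowered by both upf and CHX, the odds ratios without a fold threshold were 1.29, 1.29 and 1.58 at 15, 30 and 90 min, and 10.9, 13.5 and 2.86 with upf at the same time, which shares libraries. With an estimated correlation 48 list calls were lost, and fry tested the NMD factors of upf at 45 min the other way (adjusted p = 0.0273).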

Other observations

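The tests of the stop read from the longest coding sequence, of CHX among transcripts unmoved by heat and of transcripts raised by heat, both tests with the annotated stop and the comparison with transcripts not raised by heat, were chosen only after the result was seen; that of neighbouring genes was written before. Transcripts encoded by the organelles took different shares of the counts under heat, and these shares were not tested. The 122 mitochondrial-encoded genes took 0.0187% of all counts in unheated wild type and 0.324 ± 0.0352% at 90 min (mean ± SD, n = 3), and in upf 0.0161% and 0.450 ± 0.0534%. With CHX they stood at 0.289% at 90 min. The 88 plastid-encoded genes went from 1.36 ± 0.391% to 0.420 ± 0.172% in wild type and from 1.17 to 0.740% in upf, with 0.336% after 90 min with CHX. The genes of the heat lists took 3.81, 14.3 and 19.8% of the counts at 15, 30 and 45 min in wild type, and 3.00, 8.95, 12.8 and 10.7% at 15, 30, 45 and 90 min with CHX.

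Annotated coding sequences can hide an early stop where a splice form is given another start codon, so a hypothesis is that NMD acts on the stop reached from the start codon of the gene's longest coding sequence. Read that way, 46.3% (668 of 1442) of transcripts raised in usage in upf for the mean had a stop over 50 nt before the last junction, against 24.6% (342 of 1392) of those lowered and 17.5% of those not called. The odds ratio was 2.65 (95% interval 2.25 to 3.12; Fisher's exact test, 2-sided, adjusted p = 8.5e-33), and 3.90, 6.15, 1.83, 4.58 and 3.55 at 0, 15, 30, 45 and 90 min. These values are in line with the hypothesis, which was found on the same data.

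With CHX early stops were more frequent among transcripts lowered in usage than among those raised, and in both more frequent than among those not called (28.0% of raised, 33.3% of lowered and 17.73% of the others for the mean with the stop from the longest coding sequence). For the order of lowered and raised a hypothesis was that CHX held back the splice changes that heat brings; among transcripts not called under heat the odds ratio for the mean CHX effect was 0.793 with the stop from the longest coding sequence (Fisher's exact test, 2-sided, p = 0.0212) and 0.712 with the annotated stop (Fisher's exact test, 2-sided, p = 0.00819), but with 26.9% of 4-fold usage changes called in simulated data such transcripts can still have moved with heat, so this stays open. With the former stop it was 0.456 at 30 min but 1.64, 1.21 and 1.06 at 15, 45 and 90 min, so among these transcripts that order was seen at 30 min alone of the single times. Over all transcripts the odds ratio with that stop was 0.778 (adjusted p = 0.00077) for the mean, and 1.53, 0.589, 1.03 and 0.978 at 15, 30, 45 and 90 min. With the annotated stop over all transcripts it was 0.528, 0.635, 0.826 and 0.718 at these times.

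Whether transcripts raised by heat include ones that NMD holds down stays open: of those raised in wild type at 45 min with an early stop read from the longest coding sequence, 3.301% (17 of 515) were raised in upf at 30 min, against 0.69984% (9 of 1286) of the others (odds ratio 4.84, 95% interval 2.02 to 12.4, Fisher's exact test, 2-sided, p = 9.5e-05). With the annotated stop 7 of 279 and 21 of 1697 were raised (odds ratio 2.05, 95% interval 0.730 to 5.07, Fisher's exact test, 2-sided, p = 0.102). These 2 intervals overlap, and whether the excess depends on the choice of stop was not tested. With the stop from the longest coding sequence, transcripts not raised by heat gave 319 of 3622 and 456 of 15291 (odds ratio 3.14, 95% interval 2.701 to 3.65), so early stops went with upf at large and the intervals overlap. Among transcripts with such a stop those raised by heat were raised in upf less often than those not raised by heat (odds ratio 0.354, 95% interval 0.202 to 0.582). Transcripts without such a stop went the same way, with 9 of 1286 against 456 of 15291, so this was not particular to early stops. Usage calls in upf at 30 min leaned on 1 library, 993 passing without upf replicate 3 against 1635. The tests in this paragraph were not rerun without it.

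Variants linked to the mutated loci were tested by the genes around them. Of the 80 tested genes within 20 on either side of UPF1 and UPF3, 6 were called in upf for the mean, none of 40 at UPF1 and 6 of 40 at UPF3, and 66.7% of 10000 random pairs of places held as many, so no excess was seen at this size.

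Splits of the libraries into other groups were refitted for each comparison, and what they should show was written down only after the results were seen. For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10, the real split, had as many calls. The highest others for genes were 2, 1, 4 and 0 in wild type at 15, 30, 45 and 90 min (real 2943, 5869, 6935 and 7413), 1, 1, 0 and 0 in upf (2632, 5050, 6045 and 6447), 5, 15, 19, 2 and 3 for upf against wild type (1549, 1589, 2031, 2154 and 2242) and 0, 2, 81 and 203 for CHX (982, 3118, 3028 and 3373). For usage they were 13, 24, 48 and 29 in wild type (756, 3315, 3955 and 3834), 26, 128, 171, 174 and 198 for upf against wild type (478, 765, 1635, 1380 and 1512) and 43, 49, 685 and 101 for CHX (231, 1570, 1480 and 1364). For the means 1 of 100 splits, the real one, reached the count, the smallest share that 100 splits can give, so chance alone is unlikely. The counts were 1781 against a highest other of 670 genes for upf, 2226 against 733 for CHX, and in usage 3137 against 479 and 3882 against 1113.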
